A study of Homo sapiens with 68 samples.

How the data were processed

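Small RNA was sequenced from 2 human cell lines, HepG2 (hepatocellular carcinoma) and K562 (chronic myeloid leukaemia), after lentiviral delivery of shRNAs against 13 RNA-binding proteins or of a non-targeting shRNA. Small RNA was isolated with the mirVana kit and made into Illumina TruSeq small RNA libraries, per the labels' protocols. The 68 libraries come in 2 count tables, here called set 1 and set 2. Each knockdown has 2 libraries in each line, and each line has 4 non-targeting libraries in each set.

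The deposited values are raw read counts for each mature miRNA feature of miRBase version 20 on the hg19 genome build, made with featureCounts 1.5.0-p1, per the file headers. The counts are per feature, reads with several alignments were counted at each, reads overlapping several features were counted for each, and no strand option was set, per the file headers. The same headers record trimming of poly(A) and adapters, removal of reads that matched a repeat index and a Bowtie alignment. The submitters' processing notes name cutadapt, Bowtie 1.0.0, Bowtie 1.1.1 and featureCounts. Each table lists 2794 features under 2576 accessions. Of these accessions 168 are listed at several loci (386 features), where the counting cannot tell the copies apart. Another limit is strand: 138 features overlap a feature on the opposite strand, and reads of such partners were counted for both. No count was seen in any library for 1058 features.

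Library columns were matched to samples by the names in their headers. In set 1 the control headers give a control number (1 or 2) and a number 1 or 2 within it, while the labels number the control samples 1 to 4. The files do not pair these numberings, so the libraries are called a to d here, in column order, and enter as members of their group. All count columns were matched, and each header also holds a sample sheet number.

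The files give accessions and hg19 positions but no miRNA names. Of the listed IDs, 0 matched the reference gene table used here, which is on another build (GRCh38). A match of positions to that other build was tried and discarded, since the builds differ; no value below uses it and no miRNA name is given. The planned tests that need names were therefore not run: the let-7 family test in LIN28B knockdown, the other tests among the 27 name lists fixed before the data were examined (0 members matched), and values of individually listed miRNAs. No feature or region below is assigned to a family. For the same reason the text names 4 IDs: for each set, the feature with the highest and the one with the lowest log2 fold change among those the naming rule takes. That rule, fixed before the data were examined, takes up to 6 features per direction and comparison with adjusted p under 0.05, a mean of at least 10 CPM (counts scaled to library size) and both knockdown libraries beyond all 4 controls. The restriction to 4 IDs, each at 1 locus with no overlap on the opposite strand, was chosen after their values were seen.

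Each knockdown was compared with the 4 non-targeting libraries of its line and set, giving 26 comparisons, by edgeR 4.0.16 (R 4.3.3) with its quasi-likelihood test. All libraries of a line and set entered 1 fit with group as the only term, TMM scaling and the filterByExpr filter. Benjamini-Hochberg adjustment ran over the features tested in a comparison, with a threshold of 0.05 and no fold minimum. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Fold changes are relative to the TMM scaling, which assumes that most features do not change. The same test compared the non-targeting libraries of both lines and, as an interaction contrast in a joint fit, the effect of each knockdown between lines.

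Neighbouring features were grouped from the files' own positions. Features of 1 strand at most 70 bases apart were read as 1 hairpin and those at most 10000 bases apart as 1 region. Regions with at least 3 tested hairpins were tested with camera (limma 3.58.1, preset correlation 0.01), giving 13 regions and 278 tests with 1 adjustment over all. This grouping and its minimum were chosen after the data were examined. The minimum was lowered from at least 5 tested accessions (6 regions, 120 tests) after that version's calls, and miRNA names from the discarded match, had been seen. Both versions are reported. The chromosome 9 region discussed for LIN28B is eligible only with the lower minimum, so its choice was not blind.

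Agreement between lines was measured as Spearman's correlation of log2 fold changes across features, with exact permutation of the protein labels. Comparisons that share controls were set beside 50 simulations of unchanged groups, beside controls split 2 and 2 and beside the overlap of independent lists. Duplicate libraries were sought with a chi-square statistic over features with at least 20 counts. Its lowest value per degree of freedom was 3.06, so no pair of libraries of a group was as close as sampling noise.

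Library totals ran from 1029669 to 2839209 counts in HepG2 set 1, from 2458666 to 14648311 in K562 set 1, from 1658061 to 5422477 in HepG2 set 2 and from 2986746 to 8941629 in K562 set 2. Tests were checked on simulated libraries with 200 changed features. For BUD13 in HepG2 78.8% of tested features changed by 1 log2 unit were recovered among 349 features, and for BUD13 in K562 76.7% among 267. For HNRNPM the shares were 21.6% among 397 features in HepG2 and 69.7% among 286 in K562. At 2 log2 units they were 94.1%, 97.2%, 86.1% and 97.1% in the same order. In the simulated HNRNPM knockdown of HepG2, camera also called 1 region that had not been shifted.

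Alternatives were RLE size factors, total counts alone, no low-count filter, a mean CPM of at least 10, DESeq2 1.42.0, only the groups compared, the other knockdowns as reference, the replicate number as a block in set 2, and leaving out each library. Alternatives chosen after the data were examined were summed copies, arms of hairpins without shared reads, the header number as a block in set 1, a term for a split seen among the set 2 libraries of HepG2, an estimated correlation in camera, and the other region minimum. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the plots.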

Results

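Mature miRNA levels were measured in HepG2 and K562 cells after depletion of 13 RNA-binding proteins, to find which of these proteins affect miRNA levels. Set 1 held 8 proteins (BUD13, DDX3X, DKC1, LARP4, LARP7, LIN28B, RBFOX2 and SLTM) and set 2 held 5 (HNRNPM, ILF3, PRPF8, PTBP1 and SF3B4). Each knockdown had 2 libraries per line, set against 4 non-targeting libraries of the same line and set. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The level of each depleted protein or its mRNA was not measured in these files, so the depletions themselves were not checked. Library totals lay between 1029669 and 14648311 counts.

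The number of features that changed per knockdown ran from 11 to 121 by edgeR's quasi-likelihood test. Where both arms of a hairpin changed in a comparison, they usually moved in the same direction: of 172 such cases, 160 had the same direction and 12 opposite directions. In each comparison most hairpins with both arms tested were not such cases. The highest number was 19 of 77, for DKC1 in HepG2. Some hairpins share reads with another locus or the opposite strand; without them there were 95 cases, 87 with the same direction and 8 with opposite directions. The correlation between arms across the latter hairpins was above 0 in 26 of the 26 comparisons (0.155 to 0.826), where hairpins are not independent replicates and some recur between comparisons. The biological coefficient of variation was 0.106 in HepG2 set 1, 0.110 in K562 set 1, 0.333 in HepG2 set 2 and 0.173 in K562 set 2, so counts of changed features are not comparable between fits. Scaling by total counts instead of TMM shifted the median of all features by between −0.47 and 0.05 on the log2 scale, and RLE size factors by between −0.08 and 0.12; directions below are relative to TMM.

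**Figure D1:**
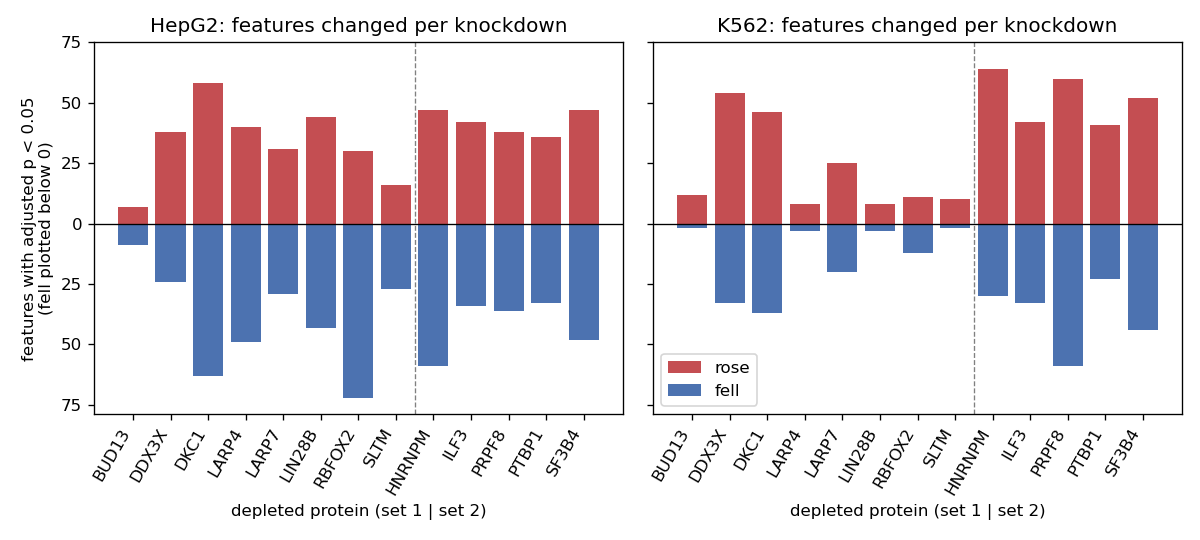
Features that rose (bars above 0) or fell (bars below 0) in each knockdown against non-targeting libraries, by edgeR's test; the vertical axis counts features and the dashed line parts set 1 from set 2. The highest count was 121 for DKC1 in HepG2 and the lowest was 11 for LARP4 and for LIN28B in K562.

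In set 2 the HepG2 libraries divided into 2 sides. The gap between control replicates 1 and 3 on the one side and 2 and 4 on the other was 0.887 log2 units (root mean square over features), against at most 0.388 for any such division of controls in the other fits. Side A held 7 of the 14 HepG2 libraries, namely these 2 controls, both HNRNPM libraries, both PRPF8 libraries and ILF3 replicate 2. In K562 only PRPF8 replicate 1 scored above the midpoint, at 0.745 of the gap. HepG2 set 2 counts are therefore given with side as a term beside the group as well. Sides were read from the same counts, so higher counts and smaller p-values with that term are not stronger evidence. The libraries of HNRNPM, PRPF8, PTBP1 and SF3B4 each lay on 1 side. Only the controls and the ILF3 libraries therefore inform the side effect.

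**Figure D2:**
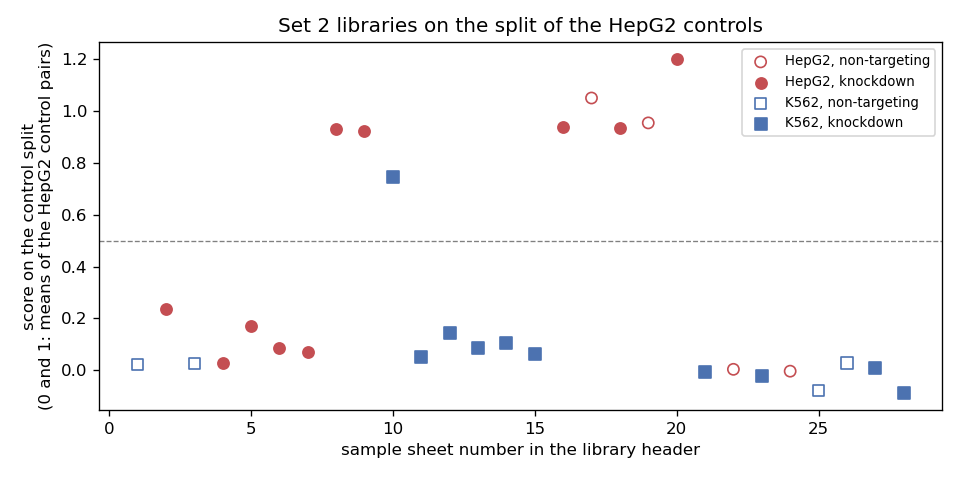
Score of each set 2 library on the division seen among the HepG2 controls, against the sample sheet number in its header; 0 and 1 are the means of the control pairs, K562 scores are relative to the K562 controls, and the dashed line marks the midpoint. Of the 28 libraries 8 lie above the line, 1 of them from K562 at 0.745.

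Depletion of BUD13, a subunit of a complex that takes part in pre-mRNA splicing, changed few features against the controls. In HepG2 7 features rose and 9 fell of 340 tested, and in K562 12 rose and 2 fell of 273; 55 and 64 had an unadjusted p under 0.05. Against the other knockdowns 44 changed in HepG2 and 37 in K562, and with only the 2 groups fitted 48 in K562; without a low-count filter 7 and 1 changed. In the chromosome 13 region from 92002872 to 92003636 (hg19, plus strand), 2 of 9 features fell in HepG2 and the median log2 change was −0.387 (camera, adjusted p = 0.00764). That call was lost with an estimated correlation (camera, adjusted p = 0.517) and against the other knockdowns (median −0.244, adjusted p = 0.0544). Scaling by total counts gave 1 rise and 13 falls in HepG2 and 3 rises and 2 falls in K562, and RLE gave 6 and 2 in K562. The HepG2 count was 1 without replicate 1, 9 and 5 without control libraries b and d, and 0 by edgeR without replicate 2, when 38 features had an unadjusted p under 0.05. The K562 count was 2 and 6 without replicates 1 and 2, and 7 and 8 without control libraries a and b.

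DDX3X is a DEAD-box RNA helicase. After its depletion 38 features rose and 24 fell in HepG2, and 54 rose and 33 fell in K562. Among features with a single locus, the largest K562 rise of set 1 was that of MIMAT0000076 (chromosome 17, 57918634 to 57918655, plus strand, hg19), from 4510 ± 200.2 CPM (SD, n = 4) to 20200 ± 197 CPM (SD, n = 2), a log2 change of 2.16 (SE 0.08; edgeR, adjusted p = 1.36e-15). In HepG2, where it stood at 112900 ± 6849 CPM in controls, it rose by 0.46 (edgeR, adjusted p = 0.00578), and the difference between lines was −1.55 (HepG2 minus K562; edgeR interaction, adjusted p = 2.16e-06). The chromosome 19 regions from 52195871 to 52196580 (3 of 6 features) and from 13947103 to 13947465 (3 of 5) held only rises in K562, with medians of 0.505 and 0.469, although neither passed as a set (camera, adjusted p = 0.330 and 0.485). Total-count scaling gave 25 rises and 48 falls in HepG2. Without replicate 1 or 2 the HepG2 count was 29 or 37 (17 rises and 20 falls in the latter), and without replicate 2 the K562 count was 46.

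DKC1 encodes dyskerin, the pseudouridine synthase of H/ACA ribonucleoproteins. Its depletion gave the highest count of set 1 in HepG2, with 58 features up and 63 down, and 46 up and 37 down in K562. MIMAT0000076 rose by 1.30 in K562 (edgeR, adjusted p = 3.76e-11) and by 0.42 in HepG2 (edgeR, adjusted p = 0.00585), a difference of −0.88 (edgeR interaction, adjusted p = 0.00541). All 4 tested features of the chromosome 9 region from 97847509 to 97848367 (plus strand) rose in HepG2, with a median of 0.470, and 4 of 8 features of the chromosome X region from 49767773 to 49779278 (plus strand) fell, with a median of −0.712. Neither passed as a set (camera, adjusted p = 0.0859 and 0.134), and with total-count scaling 1 and 7 features of these regions passed in those directions. Under that scaling 34 features rose and 113 fell in HepG2, and 23 rose and 55 fell in K562. Without replicate 1 the HepG2 count was 64.

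For LARP4, a La-related protein that binds poly(A) tails, 40 features rose and 49 fell in HepG2, and 8 rose and 3 fell in K562. The K562 count was 26 with only the 2 groups fitted, 18 against the other knockdowns and 4 without a low-count filter. In HepG2 7 of 9 features of the chromosome 13 region from 92002872 to 92003636 fell, with a median of −0.767 (camera, adjusted p = 0.00742; adjusted p = 0.601 with an estimated correlation). MIMAT0031177 (chromosome 19, 11606359 to 11606382, minus strand, hg19) fell from 447 ± 39.9 CPM (SD, n = 4) to 54.2 ± 3.47 CPM (SD, n = 2), a log2 change of −3.05 (SE 0.18; edgeR, adjusted p = 5.09e-13). It also fell in K562, by 0.45 (edgeR, adjusted p = 0.0301), and the difference between lines was −2.71 (edgeR interaction, adjusted p = 7.36e-12). A fall of this feature was not particular to LARP4: it was called in 5 of 8 HepG2 and 4 of 8 K562 knockdowns of set 1, LARP4 included. In HepG2 the next largest log2 change downward in set 1 was −0.77, with DKC1. Total-count scaling gave 21 rises and 66 falls in HepG2 and 4 rises and 11 falls in K562, and RLE gave 8 and 6 in K562. The K562 count was 2 without either knockdown library.

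LARP7 is the La-related protein bound to the small nuclear RNA that holds the kinase P-TEFb. In HepG2 31 features rose and 29 fell, and in K562 25 rose and 20 fell; without a low-count filter the counts were 37 and 21. In HepG2 3 of 9 features of the chromosome 13 region fell (median −0.439) and 2 of 5 features of the chromosome 19 region from 13947103 to 13947465 rose (median 0.322), each with camera adjusted p = 0.0683; with the higher region minimum each had camera adjusted p = 0.0379, and with an estimated correlation 0.737. In K562 the chromosome 13 region held 2 rises among 11 features (median 0.138; camera, adjusted p = 0.405). Total-count scaling gave 15 rises and 20 falls in K562. Without replicate 2 the HepG2 count was 24.

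LIN28B blocks the processing of particular miRNA precursors. In HepG2 44 features rose and 43 fell after its depletion, and in K562 8 rose and 3 fell, where only the 2 groups fitted gave 25, the other knockdowns as reference 20 and a mean CPM of at least 10 gave 19. That reference lowered the HepG2 count to 33. A chromosome 9 region from 96938244 to 96941198 (hg19, plus strand) rose in both lines. In HepG2 4 of 4 features rose, with a median of 0.775 (camera, adjusted p = 0.00499; adjusted p = 0.222 with an estimated correlation), and in K562 3 of 4, with a median of 1.15 (camera, adjusted p = 2.92e-06; adjusted p = 0.0286 with an estimated correlation). Its single-locus feature, at 96941123 to 96941144, went from 646 ± 16.9 (SD, n = 4) to 1206 ± 52.0 CPM (SD, n = 2) in HepG2 (log2 change 0.90, SE 0.09; edgeR, adjusted p = 5.29e-08) and from a mean of 9.69 to one of 31.4 CPM in K562 (1.69, SE 0.18; edgeR, adjusted p = 4.18e-07). The other features of the region share their accessions with 1 or 2 further loci, where the same reads were counted. The region is eligible only with the lower region minimum, which was chosen after the data were examined. The highest median of this region among the other set 1 knockdowns was 0.178 in HepG2 and 0.384 in K562. In set 2 the HepG2 median was 0.683 for SF3B4 (camera, adjusted p = 0.906) and, with side as a term, −0.168; for HNRNPM it was 0.168 and, with side as a term, 0.795 with 2 of 4 features up. Total-count scaling gave 27 rises and 63 falls in HepG2, and 4 and 3 in K562. The HepG2 count was 25 and 31 without replicates 1 and 2; that of K562 was 7 and 5, and 7 without control library a or b.

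**Figure D3:**
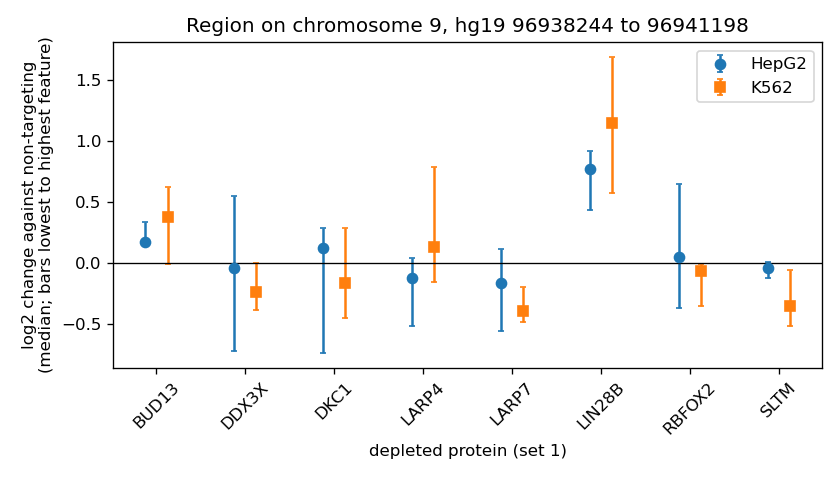
Log2 change of the chromosome 9 region in each set 1 knockdown against non-targeting libraries; points are the median over the region's tested features and bars run from the lowest to the highest feature, not an error. LIN28B has the highest median in HepG2 (0.775) and in K562 (1.15).

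RBFOX2 is a splicing regulator that binds UGCAUG motifs. Falls outnumbered rises in HepG2, with 72 against 30, and K562 gave 11 rises and 12 falls; with RLE size factors, however, the HepG2 split was 51 rises and 49 falls. In HepG2 3 of 9 features of the chromosome 13 region rose, with a median of 0.342 (camera, adjusted p = 0.0497; adjusted p = 0.737 with an estimated correlation). Falls were seen in HepG2 in 3 of 4 features of the chromosome 7 region from 129410246 to 129414828 (minus strand; median −0.559), 3 of 6 of the chromosome 19 region from 52195871 to 52196580 (−0.412) and 3 of 5 of that from 13947103 to 13947465 (−0.476), where RLE gave 1 rise and 2 falls. None of these passed as a set (camera, adjusted p = 0.291, 0.393 and 0.582). The HepG2 count was 49 without replicate 1, with 32 rises and 17 falls. That of K562 was 3 and 13 without replicates 1 and 2, and 12 and 14 without control libraries a and b.

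SLTM is a nuclear protein related to scaffold attachment factor B. In HepG2 16 features rose and 27 fell, and in K562 10 rose and 2 fell, where only the 2 groups fitted, and the other knockdowns as reference, each gave 21. The chromosome 13 region held 3 rises and no fall among 9 features in HepG2 (median 0.144; camera, adjusted p = 0.0683, and 0.0379 with the higher region minimum; adjusted p = 0.776 with an estimated correlation). RLE gave 19 rises and 21 falls in HepG2 and a count of 6 in K562, and total-count scaling gave 3 rises and 11 falls in K562. The HepG2 count was 10 without replicate 2. That of K562 was 2 and 4 without replicates 1 and 2, and 6, 4 and 6 without control libraries a, b and c.

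HNRNPM is an hnRNP protein that takes part in alternative splicing. Its depletion gave the largest single change of either set in HepG2: MIMAT0000254 (chromosome 2, 177015057 to 177015079, plus strand, hg19) went from 129 ± 24.7 CPM (SD, n = 4) to 14860 ± 286 CPM (SD, n = 2), a log2 change of 6.85 (SE 0.25; edgeR, adjusted p = 2.97e-09), and 6.68 with side as a term (edgeR, adjusted p = 2.37e-10). Its control level differed between sets: in set 1 it was 4382 ± 531.0 CPM in HepG2 and 888 ± 109 CPM in K562 (SD, n = 4 each), and in set 2 it was 36.6 ± 6.97 CPM in K562 (SD, n = 4). In K562 the feature rose by 0.75 with HNRNPM (edgeR, adjusted p = 0.0109) and in 5 of 5 knockdowns of set 2, by up to 1.14 with ILF3, and with HNRNPM the lines differed by 6.06 (edgeR interaction, adjusted p = 1.09e-10). MIMAT0003249 (chromosome 5, 148441936 to 148441957, minus strand, hg19) fell in HepG2 from 54.6 ± 2.63 to 2.16 ± 0.299 CPM, a log2 change of −4.65 (SE 0.38; edgeR, adjusted p = 3.71e-06), and −4.57 with side as a term (edgeR, adjusted p = 1.3e-06). A fall of this feature was called in 3 of 5 HepG2 knockdowns of set 2, HNRNPM included, and in 1 of 5 of K562. With HNRNPM in K562, where controls had a mean of 2.04 CPM, it was not called (−1.41; edgeR, adjusted p = 0.111). In set 1 it rose in 3 of 8 HepG2 and 3 of 8 K562 knockdowns, the latter from a control mean of 0.861 CPM. In HepG2 3 of 4 features of the chromosome 1 region from 1102504 to 1104456 (plus strand) rose, with a median of 1.09 (camera, adjusted p = 0.0859), and 4 of 4 with side as a term. In total 47 features rose and 59 fell in HepG2, and 64 rose and 30 fell in K562. The K562 count was 12 against the other knockdowns, and 60 with a mean CPM of at least 10 and with copies summed. With side as a term 162 features changed in HepG2, 69 up and 93 down, of which 104 were among the 106 with the same direction. Total-count scaling gave 29 rises and 96 falls in HepG2 and 19 rises and 86 falls in K562. Without replicates 1 and 2 the HepG2 counts were 47 and 51 and the K562 counts 34 and 31.

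ILF3 binds double-stranded RNA. In HepG2 42 features rose and 34 fell, and in K562 42 rose and 33 fell. Set against the other knockdowns, 28 changed in HepG2 and 18 in K562. Only the 2 groups fitted gave 20 in HepG2, and a mean CPM of at least 10 gave 49 in K562. The features' changes in the lines correlated at a Spearman's rho of 0.541 across features, which are not independent replicates. In K562 2 of 4 features of the chromosome 14 region from 101488408 to 101533123 (plus strand) fell, with a median of −0.577 (camera, adjusted p = 0.809). With side as a term 142 features changed in HepG2, 70 up and 72 down, including, with the same direction, the 76 called without it; the HepG2 replicates lay on different sides. Total-count scaling gave 28 rises and 51 falls in K562, where RLE gave 56 and 29. Without replicate 1 the HepG2 count was 117, and without replicates 1 and 2 the K562 counts were 47 and 40.

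PRPF8 is a core protein of the spliceosome. In HepG2 38 features rose and 36 fell, and in K562 60 rose and 59 fell, where only the 2 groups fitted gave 63 and a mean CPM of at least 10 gave 77. MIMAT0000254 rose by 2.34 in HepG2 (edgeR, adjusted p = 5.5e-05; 2.18 with side as a term) and, as in the other K562 knockdowns of set 2, in K562, by 0.97 (edgeR, adjusted p = 0.00108). MIMAT0031177 fell by 2.64 in HepG2 (edgeR, adjusted p = 5.5e-05) and by 1.82 in K562 (edgeR, adjusted p = 0.000629). For neither was a difference between lines called (1.16 and −1.04; edgeR interaction, adjusted p = 0.0973 and 0.232). In K562 3 of 3 features of the chromosome 9 region from 96938244 to 96941198 fell, with a median of −1.20, and 3 of 4 of the chromosome 14 region, with a median of −1.05 (camera, adjusted p = 0.320 and 0.375). With side as a term 120 features changed in HepG2, 58 up and 62 down, and 73 of the 74 were among them. Total-count scaling gave 21 rises and 53 falls in HepG2, and 40 and 79 in K562. Without replicates 1 and 2 the HepG2 counts were 28 and 22, and without K562 replicate 1, the library on side A, the K562 count was 90.

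PTBP1 is the polypyrimidine tract-binding protein. In HepG2 36 features rose and 33 fell, and in K562 41 rose and 23 fell. The counts were 39 and 18 against the other knockdowns, and only the 2 groups fitted gave 101 in K562. MIMAT0031177 fell by 2.05 in HepG2 (edgeR, adjusted p = 0.000284), and MIMAT0000076 rose by 1.40 in K562 (edgeR, adjusted p = 3.18e-06), where HepG2 gave 0.31 (edgeR, adjusted p = 0.315); the line differences were −1.97 and −1.36 (edgeR interaction, adjusted p = 0.0214 and 0.0262). In HepG2 2 of 3 features of the chromosome 14 region rose, with a median of 1.58 (camera, adjusted p = 0.174), but 1 with side as a term and 0 by edgeR with total-count scaling. With side as a term 114 features changed in HepG2, 64 up and 50 down, including 64 of the 69. Total-count scaling gave 18 rises and 53 falls in HepG2 and 19 rises and 80 falls in K562. Without replicates 1 and 2 the HepG2 counts were 10 and 11 and the K562 counts 34 and 31.

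SF3B4 is a subunit of the splicing factor SF3b. In HepG2 47 features rose and 48 fell, and in K562 52 rose and 44 fell; set against the other knockdowns 34 changed in each line. MIMAT0000076 rose in both lines, by 1.03 in HepG2 and 0.89 in K562 (edgeR, adjusted p = 0.00382 and 0.000114), and MIMAT0031177 fell in both, with log2 changes of −1.98 and −1.68 (edgeR, adjusted p = 0.000327 and 0.00108). In HepG2 2 of 4 features fell in each of the chromosome 19 region from 13947103 to 13947465 (median −1.31) and the chromosome 7 region from 129410246 to 129414828 (median −1.38; camera, adjusted p = 0.134 and 0.330). With the higher region minimum camera called a fall of the chromosome X region from 49767773 to 49779278 in HepG2 (median −1.99, adjusted p = 0.0379), while with the lower minimum it was not called (camera, adjusted p = 0.0683; adjusted p = 0.993 with an estimated correlation). The medians with side as a term were −0.849 for that region, −0.900 for the chromosome 19 region and −0.736 for the chromosome 7 region, where 3 features fell. With side as a term 128 features changed in HepG2, 72 up and 56 down, including 91 of the 95. Total-count scaling gave 21 rises and 89 falls in HepG2 and 21 rises and 93 falls in K562. Without replicates 1 and 2 the HepG2 counts were 32 and 47 and the K562 counts 46 and 57.

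Differences of knockdown effect between lines were tested directly as interactions. By edgeR's test 22 features differed for DDX3X, 37 for DKC1, 26 for LARP4, 22 for LARP7, 6 for LIN28B, 31 for RBFOX2, 13 for SLTM, 37 for HNRNPM, 20 for PRPF8, 24 for PTBP1 and 9 for SF3B4. The count was 0 by edgeR for BUD13 and for ILF3, where 44 and 43 features had an unadjusted p under 0.05 and DESeq2 called 4 and 17. For ILF3 side as a term gave 12, RLE and TMM within lines 8 each and total counts 6, and for PRPF8 side as a term gave 37. The side term placed no K562 library on side A, although PRPF8 replicate 1 of K562 scored above the midpoint, so that library was not adjusted for. DESeq2 called 39 for DDX3X, 60 for DKC1, 39 for LARP7, 28 for SLTM, 65 for HNRNPM, 38 for PRPF8, 50 for PTBP1 and 45 for SF3B4. Without a low-count filter edgeR gave 23 for DKC1, 6 for LARP7, 2 for LIN28B, 19 for RBFOX2 and 15 for PTBP1. The change was higher in K562 for 25 of the 26 LARP4 features, 20 of 22 for LARP7 and 12 of 13 for SLTM; with TMM factors set within each line the splits (HepG2 higher, K562 higher) were 7 and 24, 9 and 24, and 5 and 15. For HNRNPM, PRPF8, PTBP1 and SF3B4 the splits were 8 and 29, 3 and 17, 7 and 17, and 6 and 3, against 20 and 34, 12 and 18, 12 and 11, and 12 and 20 with TMM within lines. RLE gave 7 and 24 for LARP4, 11 and 25 for LARP7, 20 and 31 for HNRNPM and 12 and 18 for SF3B4. Total-count scaling gave 6 and 23 for DDX3X (9 and 13 with TMM), 9 and 11 for LARP7, 9 and 8 for SLTM, 17 and 28 for HNRNPM, 8 and 18 for PRPF8, 15 and 11 for PTBP1 and 13 and 15 for SF3B4.

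The non-targeting libraries show how the lines differ without a knockdown. In set 1 261 of 310 features differed by edgeR's test, 137 higher in HepG2 and 124 higher in K562, and in set 2 236 of 345, 128 and 108. The chromosome 13 region was higher in K562 in 10 of 10 features in each set, with summed means of 185100 CPM against 17810 in set 1 and 430100 against 26200 in set 2. The chromosome X region from 133303412 to 133304296 (minus strand) was higher in K562 in 3 of 4 features in set 1 (115800 CPM against 11130). The chromosome 9 region from 97847509 to 97848367 was higher in HepG2 in 4 of 4 features in set 1 (38000 CPM against 5622) and 3 of 4 in set 2, and the chromosome 1 region from 1102504 to 1104456 in 4 of 4 in each set (1203 CPM against 23.7 in set 1). Of 289 features tested in both sets 192 differed in both, 184 of them in the same direction. Total-count scaling gave 260 higher in HepG2 and 36 in K562 in set 1, and 265 and 51 in set 2.

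On average, knockdowns of the same protein resembled each other across lines more than those of different proteins. The lines have separate controls. In set 1 the mean Spearman's rho across 241 features was 0.252 for the same protein and 0.155 for different proteins (exact permutation of the 8 labels, one-sided p = 0.00102), and in set 2, across 254 features, 0.390 and 0.248 (exact permutation, one-sided p = 0.00833, the smallest the 120 orders can give). With side as a term in HepG2 the set 2 values were 0.363 and 0.294 (exact permutation, one-sided p = 0.00833). Single proteins ranged from −0.00153 for SLTM to 0.541 for ILF3. SLTM, LARP7 (0.083) and RBFOX2 (0.126) lay below the set 1 mean for different proteins, and HNRNPM (0.205) below that of set 2. With side as a term HNRNPM (0.191) and PRPF8 (0.224) lay below the set 2 mean for different proteins.

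Some features changed in many knockdowns of a line. MIMAT0000076 rose in 7 of 8 K562 knockdowns of set 1 and 4 of 5 of set 2, MIMAT0000254 rose in 5 of 5 K562 knockdowns of set 2, and MIMAT0031177 fell in 5 of 5 HepG2 knockdowns of set 2. The last also fell in 5 of 8 HepG2 and 4 of 8 K562 knockdowns of set 1, and in 2 of 5 K562 knockdowns of set 2. MIMAT0000254 rose in 2 of 5 HepG2 knockdowns of set 2 but fell in 4 of 8 HepG2 knockdowns of set 1. The largest of these falls was with RBFOX2 (log2 change −1.34; edgeR, adjusted p = 1.7e-05). In K562 set 1 it was called by edgeR in 0 of 8. Counting features that changed in the same direction in at least 4 of 8 or 3 of 5 knockdowns gave 45 in HepG2 set 1, 10 in K562 set 1, 47 in HepG2 set 2 and 72 in K562 set 2. Simulated unchanged groups gave at most 0. Their controls were simulated as well, as independent libraries around the control means, without the division seen in HepG2 set 2. Referred to the other knockdowns instead, the observed counts were 5, 1, 5 and 1. That reference itself holds changes shared by many knockdowns, so they partly cancel and lower counts follow from any cause. With side as a term the observed count of HepG2 set 2 was 112. The mean overlap of a pair of knockdowns was 19.5, 8.11, 35 and 46.9 features in the same order, against 7.53, 2.20, 8.45 and 13.6 for independent lists. The mean correlation of fold changes was 0.289, 0.415, 0.399 and 0.529, against 0.304, 0.364, 0.282 and 0.244 simulated. The covariance was 0.0802, 0.0965, 0.479 and 0.378, against 0.0292, 0.0363, 0.0945 and 0.0410 simulated, and with the controls split 2 and 2 it was 0.0419, 0.0546, 0.293 and 0.261. Total-count scaling changed the split of these features from 20 rises and 25 falls to 10 and 42, from 4 and 6 to 2 and 8, from 24 and 23 to 14 and 44, and from 44 and 28 to 21 and 72.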

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

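Tests of library order, of the gap among controls, of the sides of knockdown libraries, of members at several loci, of the region against other knockdowns, of its rank, and of HNRNPM against other knockdowns were chosen after the results were seen, as was the region minimum.

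Among the K562 controls of set 2, library 1 lay far from the others. It had 8941629 counts, against 4080851 to 4850409 in the others, a gap of 0.842 of the whole range, and 718 detected features, against 626 to 639, a gap of 0.859. These were 2 of 12 such tests, and chance alone singles out about 1 in 20.

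Effects differed between lines, by edgeR's interaction test, for 22 features with DDX3X, 37 with DKC1, 26 with LARP4, 22 with LARP7, 6 with LIN28B, 31 with RBFOX2, 13 with SLTM, 37 with HNRNPM, 20 with PRPF8, 24 with PTBP1 and 9 with SF3B4. Each was singled out because the tested effects of a knockdown differed between the lines. Technical and biological explanations of these differences were not tested.

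The HepG2 libraries of set 2 divided into 2 sides, which parted the controls and the ILF3 libraries but no other group. Depletion of the target proteins was not at work in the controls, which received a non-targeting shRNA. The gap among them was 0.887 log2 units (root mean square), against at most 0.388 in the other fits. The sides were defined by that gap, so its size could not decide on depletion. For the sides of the knockdown libraries depletion stays open, since the libraries of 1 of the 5 proteins lay on different sides. A library preparation batch may underlie the division. Over all set 2 libraries, K562 included, sides formed 5 runs along the sample sheet numbers. Permuting 22 blocks of neighbouring libraries of a group gave 10.5 on average (permutation p = 0.00509, one-sided). Of the K562 libraries only PRPF8 replicate 1 lay on side A, so the order of the lines on the sheet enters this p-value. The HepG2 libraries were not tested alone. The labels name no batch, and the order test was chosen after the division was seen. Sequencing depth stays open, since 2 of 7 side A libraries had totals within the range of side B. Side A totals ran from 1658061 to 5422477 counts and side B totals from 2467866 to 3700511. Side A thus reached both below and above side B, and no single total parted the sides.

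The chromosome 9 region from 96938244 to 96941198 rose in LIN28B knockdown in both lines, although with an estimated correlation the HepG2 call was lost (camera, adjusted p = 0.222) and the K562 call was not (adjusted p = 0.0286). Reads shared with listed copies at other loci are argued against for the member listed at 1 locus, which rose in 2 of 2 lines. Whether reads of similar sequences elsewhere were also counted for this member was not tested. The members at several loci gave 5 rises in 6 tests over both lines. For them the effects of the copies cannot be told apart because the same reads were counted at each. A low level of the shared controls is argued against, since the region was also called against the other knockdowns, where the lower of the medians was 0.689. Depletion of LIN28B stays open: LIN28B ranked 1 of 8 in HepG2 (exact p = 0.125, one-sided, the smallest that 8 knockdowns can give), its level was not measured, and in set 2 the HNRNPM median of the region in HepG2 was 0.795 with side as a term. The region became eligible through a minimum lowered after results and miRNA names had been seen, so this is a hypothesis.

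Changes common to the K562 knockdowns of set 2 exceeded the chance values of shared controls, with a mean covariance of 0.378 against at most 0.0595 in 50 simulations. Control libraries that differ technically cannot be told apart from a response shared by the knockdowns. With the controls split 2 and 2 the covariance was 0.261, and against the other knockdowns the HNRNPM count was 12, and either explanation predicts both values.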

How the results depend on the processing

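Tests with library side, same-side libraries, summed copies, an estimated correlation and the other region minimum, and other references or scalings for regions and for features called in several knockdowns, and the replicate block of set 1, were chosen after the data were examined.

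Depth alone did not set what was detectable: on simulated data 21.6% of features changed by 1 log2 unit were recovered for HNRNPM in HepG2 set 2 and 78.8% for BUD13 in HepG2 set 1, whose libraries were shallower. Directions of counts are relative to the scaling, which shifts all features of a comparison, so a turned majority restates that shift. The majority direction of changed features turned in 14 of 26 comparisons with total counts and in 6 of 26 with RLE size factors. For features differing between lines it turned in 3 of 13 proteins with total counts, 1 of 13 with RLE and 2 of 13 with TMM within each line. The 4 named IDs kept their direction and their call in the named comparison under every alternative run for them. Log2 changes ran from 1.54 to 2.20 for MIMAT0000076, from −3.17 to −2.68 for MIMAT0031177, from 6.34 to 6.95 for MIMAT0000254 and from −4.98 to −3.88 for MIMAT0003249. The tests of same-protein resemblance kept their direction and side of the threshold in each alternative run. For the values below that crossed a threshold or moved by over 1.5 times, the cause was not tested.

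With no low-count filter the counts of changed features were 7 for BUD13 and 37 for LARP7 in HepG2, and 1 for BUD13, 4 for LARP4 and 21 for LARP7 in K562. The same setting gave 23 features differing between lines for DKC1, 6 for LARP7, 2 for LIN28B, 19 for RBFOX2 and 15 for PTBP1, and 403 features between the control libraries of set 2. A mean CPM of at least 10 gave 19 for LIN28B, 60 for HNRNPM, 49 for ILF3 and 77 for PRPF8 in K562. Summed copies gave 8 for BUD13 and 60 for HNRNPM in K562.

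With the other knockdowns as reference the HepG2 counts were 44 for BUD13, 33 for LIN28B, 28 for ILF3, 39 for PTBP1 and 34 for SF3B4. Those of K562 were 37 for BUD13, 18 for LARP4, 20 for LIN28B, 21 for SLTM, 12 for HNRNPM, 18 for ILF3, 18 for PTBP1 and 34 for SF3B4. Features called in at least 4 of 8 or 3 of 5 knockdowns then numbered 5 in HepG2 set 1, 1 in K562 set 1, 5 in HepG2 set 2 and 1 in K562 set 2. Shared changes are also in this reference, so these lower counts follow from any cause. The chromosome 13 region with BUD13 in HepG2 had a median of −0.244 (camera, adjusted p = 0.0544).

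With only the 2 groups compared in a fit the count was 20 for ILF3 in HepG2, and in K562 48 for BUD13, 26 for LARP4, 25 for LIN28B, 21 for SLTM, 63 for PRPF8 and 101 for PTBP1.

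RLE size factors gave 8 for BUD13 and 6 for SLTM in K562, and between lines 36 for LARP7, 3 for LIN28B, 25 for SLTM, 8 for ILF3 and 30 for SF3B4. Total counts gave 5 for BUD13, 7 for LIN28B and 99 for PTBP1 in K562, and between lines 6 for ILF3 and 28 for SF3B4. TMM within each line gave 1 for BUD13, 20 for SLTM, 8 for ILF3 and 32 for SF3B4 between lines. DESeq2 gave, between lines, 4 for BUD13, 39 for DDX3X, 60 for DKC1, 39 for LARP7, 28 for SLTM, 65 for HNRNPM, 17 for ILF3, 38 for PRPF8, 50 for PTBP1 and 45 for SF3B4.

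With library side as a term the HepG2 counts of set 2 were 162 for HNRNPM, 142 for ILF3, 120 for PRPF8 and 114 for PTBP1, with 112 features called in at least 3 of 5 knockdowns, and between lines 12 for ILF3 and 37 for PRPF8. With only libraries of the same side they were 184 for HNRNPM, 154 for PRPF8, 128 for PTBP1 and 145 for SF3B4. In the side fits between lines all K562 libraries, PRPF8 replicate 1 included, entered as side B. Sides were read from the same counts, so higher counts with them are not stronger evidence.

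With the replicate number as a block in set 2 the HepG2 counts were 52 for HNRNPM, 8 for ILF3, 26 for PRPF8, 7 for PTBP1 and 39 for SF3B4. Only controls have replicates 3 and 4, so each of these stood alone in its block and added nothing to the contrast. The contrast rested on control replicates 1 and 2, which in HepG2 lay on different sides. In set 1 the headers number control libraries 1 or 2 within each of 2 control numbers, and a block on that number moved no count by over 1.5 times, nor did the block of set 2 move any other count so. Differences between replicates 1 and 2 correlated above 0.1 in 3 of 28 pairs of knockdowns in HepG2 set 1, 7 of 28 in K562 set 1, 2 of 10 in HepG2 set 2 and 0 of 10 in K562 set 2, so the numbers were not read as pairs.

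With an estimated correlation camera lost 4 of its 5 calls: chromosome 13 with BUD13 (median −0.387, adjusted p = 0.517), LARP4 (−0.767, adjusted p = 0.601) and RBFOX2 (0.342, adjusted p = 0.737), and chromosome 9 with LIN28B in HepG2 (0.775, adjusted p = 0.222).

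Leaving out 1 library at a time, where a lone knockdown library is assumed to vary like the other groups, the HepG2 counts ran from 0 by edgeR (38 at an unadjusted p under 0.05) to 11 for BUD13, 29 to 59 for DDX3X, 64 to 117 for DKC1, 62 to 86 for LARP4, 24 to 58 for LARP7, 25 to 75 for LIN28B, 49 to 106 for RBFOX2, 10 to 40 for SLTM, 47 to 112 for HNRNPM, 62 to 117 for ILF3, 22 to 69 for PRPF8, 10 to 80 for PTBP1 and 32 to 100 for SF3B4. Those of K562 ran from 2 to 15 for BUD13, 46 to 84 for DDX3X, 60 to 80 for DKC1, 2 to 11 for LARP4, 32 to 55 for LARP7, 5 to 13 for LIN28B, 3 to 19 for RBFOX2, 2 to 10 for SLTM, 31 to 84 for HNRNPM, 40 to 72 for ILF3, 90 to 163 for PRPF8, 31 to 65 for PTBP1 and 46 to 87 for SF3B4. Features differing between control libraries ran from 248 to 263 in set 1 and from 231 to 254 in set 2.

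Other settings for the let-7 family test and the other name lists were not run, since the files pair no ID with a name.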

Other observations

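The tests of other splits of the control libraries were chosen after the results were seen. Between HepG2 and K562 controls 261 features differed in set 1 and 236 in set 2, and of the 35 splits of the 8 libraries 1, the real one, gave as many in each set. The highest count of any other split was 0 by edgeR in each set, with at most 9 and 19 features at an unadjusted p under 0.05. Each other split mixes the lines within its groups, which widens their spread. A low count there could be foreseen, so it does not exclude chance and says nothing about how much libraries of a line vary. Other splits were not run with DESeq2.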
